A study of Mus musculus with 8 samples.

How the data were processed

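Liver RNA of 8 male ob/ob mice was sequenced, 4 given Ad-GFP and 4 labelled Ad-Inpolin. Reads were trimmed with cutadapt 1.9.3, aligned to mm10 with HISAT2 2.0.4 and quantified with Cufflinks and Cuffdiff (versions not stated), per the submitters' processing notes. The authors deposited 1 table of FPKM for the whole series, per the file headers, with 22564 protein-coding genes identified by Ensembl ID. In the copy used here 1 line of the table held no content and is not analysed here. How the FPKM were scaled between libraries is not stated, and they were used as the authors scaled them. The table holds no counts and no test results of the authors.

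Of the gene IDs, 21839 (96.8%) were found in GENCODE release M21 on GRCm38, all on the same chromosome; 36.7% of these had identical start and end, and for 90.0% the locus in the table holds the gene within a margin of 2000 bases. The coordinates printed are those of the release for genes it holds. The table has 83 duplicated symbols, and each was tested as its own gene. Symbols follow the table except for Adgre1, Msmo1, Angptl8 and Jchain, which are listed there as Emr1, Sc4mol, Gm6484 and Igj and were found by ID. All 15 housekeeping genes checked were found and had 0 libraries at 0, while 6974 genes were at 0 in all 8. In 64 cases a gene was below 0.01 FPKM in 1 library with a mean of at least 5 in the other 7, and 16 of these, Alb among them, were in Ad-Inpolin 3. Genes with values of 0 in some libraries are given by liver.

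Read totals are not in the files used, so depth was estimated only relative to Ad-GFP 1. The ratios of low genes (mean FPKM at most 0.3) between libraries were placed on whole-read steps with a tolerance of 0.01 log2 units. Between 15.6% and 23.4% of them fell on such steps at the best offset, against 4.3% to 4.6% at other offsets. Only a narrow range of offsets was searched, so a depth lower by a whole-number ratio could be read as near that of Ad-GFP 1. Precision is given by the SD over 4 livers and the SE of the fit.

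FPKM were converted to log2(FPKM + 1), and the 11814 genes with a mean of at least 0.5 FPKM over the 8 livers were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust). The contrast was Ad-Inpolin against Ad-GFP with no covariate, the tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The residual degrees of freedom were 6. Log2 fold changes relative to the median gene subtract the median of -0.117 over all genes, a choice made after seeing that median. Orm1, Orm2 and Orm3 also had an exact permutation test of the difference of group means over 70 assignments.

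Gene lists (33, with 518 entries) were fixed before the data were examined, as were the samples, the tests, the rule for naming genes and the alternatives, except those marked below. With at least 3 tested members required, 31 lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 31. Exocrine pancreas markers had 0 tested members, and the orosomucoid family was not tested as a list. Orm2 was left out of other lists. For 1 list entry, Tf, no gene was found under that symbol, which does not show that the gene is absent from the table. Members were also adjusted over their list alone. Named genes were the orosomucoid genes, 12 genes of the question, up to 10 genes in each direction with the largest changes among those that passed and did not overlap, filled up with those of the smallest p, and up to 4 members of each list by p. Gene models were passed over.

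All 35 splits of the 8 livers into 4 and 4 were run with the same fit. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, quantile scaling, median-ratio scaling, the replicate number as a block, library weights, limma without trend and robust, a 2-fold or an unadjusted threshold, camera with estimated correlations, the rotation test fry (a list against no change in the FPKM as deposited, not against other genes), and leaving out each liver in turn. After the data were seen, 1 more was added, leaving out Ad-Inpolin 3 with median-ratio scaling. The procedure was tested on simulated data with 200 of 11814 genes changed in 10 runs. It recovered 18.36% of genes changed 1.5-fold, 58.36% changed 2-fold and 93.64% changed 4-fold, with 4.4 false calls per run. A simulated list changed 1.5-fold was called in 10 of 10 runs, with 1 other list called over all runs. The simulated genes varied independently of each other, whereas the estimated correlation within the called lists reached 0.71 (p53 targets). The simulated runs therefore do not show how often lists of correlated genes are called falsely. After the data were seen, the 50-base stretches of the orosomucoid transcripts and of 4 called genes with known relatives were looked up in the transcripts of all other genes of the GENCODE release. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.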

Results

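Liver RNA was measured in 8 male ob/ob mice, 4 in each of 2 groups. These mice lack the fat hormone leptin, overeat and develop obesity with a fatty liver. At 8 to 12 weeks of age each mouse received 1e+09 plaque-forming units of an adenovirus, a vector that delivers genes mainly to hepatocytes, into the tail vein, and the liver was taken on day 12. The control virus carried GFP, a fluorescent protein. The sample labels call the other group Ad-Inpolin, whereas the series description calls its non-GFP virus Ad-ORM2. No label equates these names, so the Ad-Inpolin livers are read here as the ORM2 group because only 2 groups exist. ORM2 is orosomucoid 2, an acute-phase glycoprotein secreted by the liver. The stated purpose was to find target genes of ORM2 in relation to liver fat, and the series title names de novo lipogenesis, the making of fatty acids from acetyl-CoA.

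The authors' table gives an FPKM value for each of 22564 protein-coding genes in each liver. The FPKM of a library summed to between 576479 and 594884, and between 8498 and 9780 genes were listed at 0. Ad-GFP libraries had at most 8789 genes at 0, against 8704, 9356, 9780 and 9174 in Ad-Inpolin 1 to Ad-Inpolin 4. Read totals are not given in the sources used here, so the absolute depth is unknown. The value of 1 read among low genes put the depth of the libraries at 84.1% to 107.5% of that of Ad-GFP 1. It was 94.6% to 107.5% in Ad-GFP and 84.1% to 94.3% in Ad-Inpolin libraries, so the groups did not overlap, by a narrow margin. Only depths near that of Ad-GFP 1 were searched, so this estimate cannot exclude a much lower depth. Estimated depth and genes at 0 thus differed with group, and what this does to group differences of low genes was not tested. Ad-Inpolin 3 stood apart from the other livers. Its mean correlation with the other 7 libraries was 0.9468, against 0.962 to 0.967 for the others, and it had the 9780 genes at 0. The median gene was lower in the Ad-Inpolin group by a log2 fold change of -0.12, with 69.4% of genes below 0, and this median was -0.0009 after quantile scaling. Much of it lay in Ad-Inpolin 3, where the median gene was at -0.29 from the Ad-GFP mean, against -0.06, -0.10 and -0.02 in Ad-Inpolin 1, Ad-Inpolin 2 and Ad-Inpolin 4; without Ad-Inpolin 3 the median was -0.06, with 61% of genes below 0. Alb, the albumin gene, is named because its values were seen: it was listed at 0 in Ad-Inpolin 3 and lay between 20120 and 29008 FPKM in the other 7 libraries. The log2 fold changes below are therefore given relative to the median gene, with the SE of the fit, while each adjusted p tests the change in the FPKM as deposited.

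Orm2, the gene named for the virus, rose in all 4 Ad-Inpolin livers. Its level was 66.5 ± 22.0 FPKM in the Ad-GFP livers and 794 ± 296 FPKM in the Ad-Inpolin livers (SD, n = 4), an 11.9-fold difference of the means. The Ad-Inpolin livers held 1031, 780, 381 and 982 FPKM, the 381 FPKM being that of Ad-Inpolin 3, and the Ad-GFP livers 96.7, 63.2, 62.2 and 43.8 FPKM. The log2 fold change was 3.63 ± 0.31 (adjusted p = 0.00467 by limma), and the two-sided exact permutation p was 0.0286, the smallest that 70 assignments allow. Orm1, a close paralog that was already abundant, was at 976 ± 208 FPKM in Ad-GFP and 1440 ± 538 FPKM in Ad-Inpolin livers (SD, n = 4) and did not pass (adjusted p = 0.439). Orm3 was near 7 FPKM in both groups, at 6.56 ± 3.03 and 7.47 ± 2.36 FPKM (SD, n = 4; adjusted p = 0.820). The 3 genes lie side by side on chromosome 4 of mm10, with Orm2 (ENSMUSG00000061540) at 63362449 to 63365878 on the plus strand. Of the 50-base stretches of the Orm2 transcript 20.4% also occur in Orm1 and 3.6% in Orm3, so the division of reads from these stretches is uncertain, and the values do not separate virus-borne from native Orm2 transcripts.

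**Figure D1:**
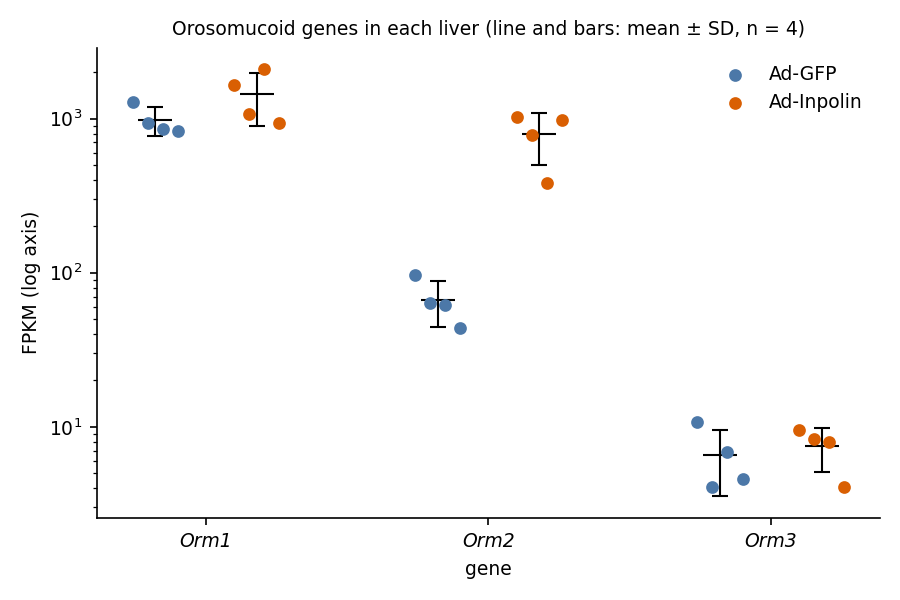
FPKM of Orm1, Orm2 and Orm3 in each liver on a log axis, Ad-GFP in blue and Ad-Inpolin in orange, with the mean and SD of the 4 livers of a group in black. Orm2 lay between 43.8 and 96.7 FPKM in Ad-GFP livers and between 381 and 1031 FPKM in Ad-Inpolin livers, whereas the groups overlapped for Orm1 and Orm3.

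Beyond Orm2, few single genes separated the groups by the test. In all, 11 of 11814 genes passed the threshold, 5 higher and 6 lower in Ad-Inpolin livers. Moxd1, a relative of dopamine beta-hydroxylase, rose from 0.780 ± 0.583 to 19.0 ± 10.8 FPKM. Cyp7b1, which hydroxylates oxysterols in the alternative route of bile acid synthesis, rose from 69.4 ± 11.7 to 154 ± 17.4 FPKM, a log2 fold change of 1.26 ± 0.13 (adjusted p = 0.0146). Selenbp2, a selenium-binding protein, rose from 201 ± 44.3 to 425 ± 28.4 FPKM, and Mup11, a major urinary protein that carries pheromones, from 146 ± 28.7 to 348 ± 72.8 FPKM. Cbr1 and Cbr3, carbonyl reductases, fell from 92.4 ± 6.04 to 39.7 ± 8.25 FPKM and from 7.39 ± 2.62 to 1.41 ± 0.499 FPKM. Gstm1, a glutathione S-transferase, fell from 544 ± 33.3 to 299.6 ± 50.2 FPKM. Acot2, a mitochondrial acyl-CoA thioesterase, fell from 10.3 ± 1.61 to 3.54 ± 1.09 FPKM, and Bola2, which takes part in the handling of iron-sulfur clusters, from 12.7 ± 2.09 to 3.39 ± 1.82 FPKM. The last of the 11, 2010003K11Rik, fell from 22.9 ± 2.58 to 7.14 ± 1.64 FPKM; the naming rule passes over such gene models, and it is named because its value was seen (all SD, n = 4).

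The log2 fold changes of the named calls were 3.49 for Moxd1, 1.36 for Mup11, 1.22 for Selenbp2, -1.65 for Cbr3, -1.59 for Bola2, -1.23 for Acot2, -1.10 for Cbr1 and -0.75 for Gstm1. On mm10, Moxd1 (ENSMUSG00000020000) lies on chromosome 10 at 24223517 to 24302790, Cyp7b1 (ENSMUSG00000039519) on chromosome 3 at 18071950 to 18243338, and Selenbp2 (ENSMUSG00000068877) on chromosome 3 at 94693556 to 94704413. Cbr1 (ENSMUSG00000051483) at 93605853 to 93610505 and Cbr3 (ENSMUSG00000022947) at 93683215 to 93690990 are neighbours on chromosome 16. Of the 50-base stretches of their transcripts 87.7% for Mup11, 27.7% for Acot2, 19.9% for Gstm1 and 4.0% for Cbr1 also occur in another gene, so part of the reads of these genes, most for Mup11, cannot be placed by sequence alone. The next named genes by p did not pass. On the higher side they included Cd200, an inhibitory membrane ligand of myeloid cells, the complement genes C8b and C2, the chemokine Ccl25, the steroid dehydrogenase Hsd3b5 and Mup7. On the lower side they included Ppp2r2d, Fabp4, Gsta1, Cdc42ep2 and Ccnb1. Their adjusted p lay between 0.0568 and 0.0926, and for each of these 11 genes the 4 values of one group lay above the 4 of the other. Such separation was found for 932 genes (7.89%, against 2.86% by chance for a single gene), 187 higher and 745 lower in Ad-Inpolin livers. This count is on the FPKM as deposited, in which the median gene was lower in Ad-Inpolin livers. It was not repeated after scaling or over other splits, so the excess and its direction cannot be told apart from that shift. Nor can they be told apart from the lower estimated depth of the Ad-Inpolin libraries.

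At an unadjusted p under 0.05, 314 genes were higher and 1110 lower, and these became 590 and 711 with quantile scaling and 547 and 692 with median-ratio scaling, which also left 3 higher and 2 lower genes past the adjusted threshold. Orm2 passed in all 18 alternatives, whereas the highest adjusted p over them was 0.0737 for Moxd1 and 2010003K11Rik, 0.0751 for Cbr1, 0.0951 for Cyp7b1, 0.103 for Selenbp2, 0.123 for Mup11, 0.148 for Bola2, 0.168 for Cbr3 and Gstm1 and 0.218 for Acot2. The count of 11 depended on single livers: it was 1 without Ad-GFP 1, without Ad-GFP 2 or without Ad-GFP 3 (Orm2 each time), 5 without Ad-GFP 4, 2 without Ad-Inpolin 1, 8 without Ad-Inpolin 2, 6 without Ad-Inpolin 3 and 57 without Ad-Inpolin 4. Among those 57, Cd200, C8b, Ccl25, Hsd3b5, Ppp2r2d, Fabp4, Gsta1 and Ccnb1 passed with adjusted p between 0.00289 and 0.0428. Of these genes Gsta1 also passed without Ad-Inpolin 2 (adjusted p = 0.0259). With library weights Cd200, C8b, Ppp2r2d, Fabp4, Gsta1, Ccnb1 and also Cdc42ep2 passed (adjusted p between 0.0279 and 0.0376). With the filter at 5 FPKM C8b passed at 0.0468 and Ppp2r2d, Fabp4 and Gsta1 at 0.0334, with a pseudocount of 0.1 Cd200 and Ppp2r2d at 0.0494, and with quantile scaling Fabp4 and Cdc42ep2 at 0.0445. Over their alternatives the adjusted p of the 8 genes reached 0.218 to 0.296.

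**Figure D2:**
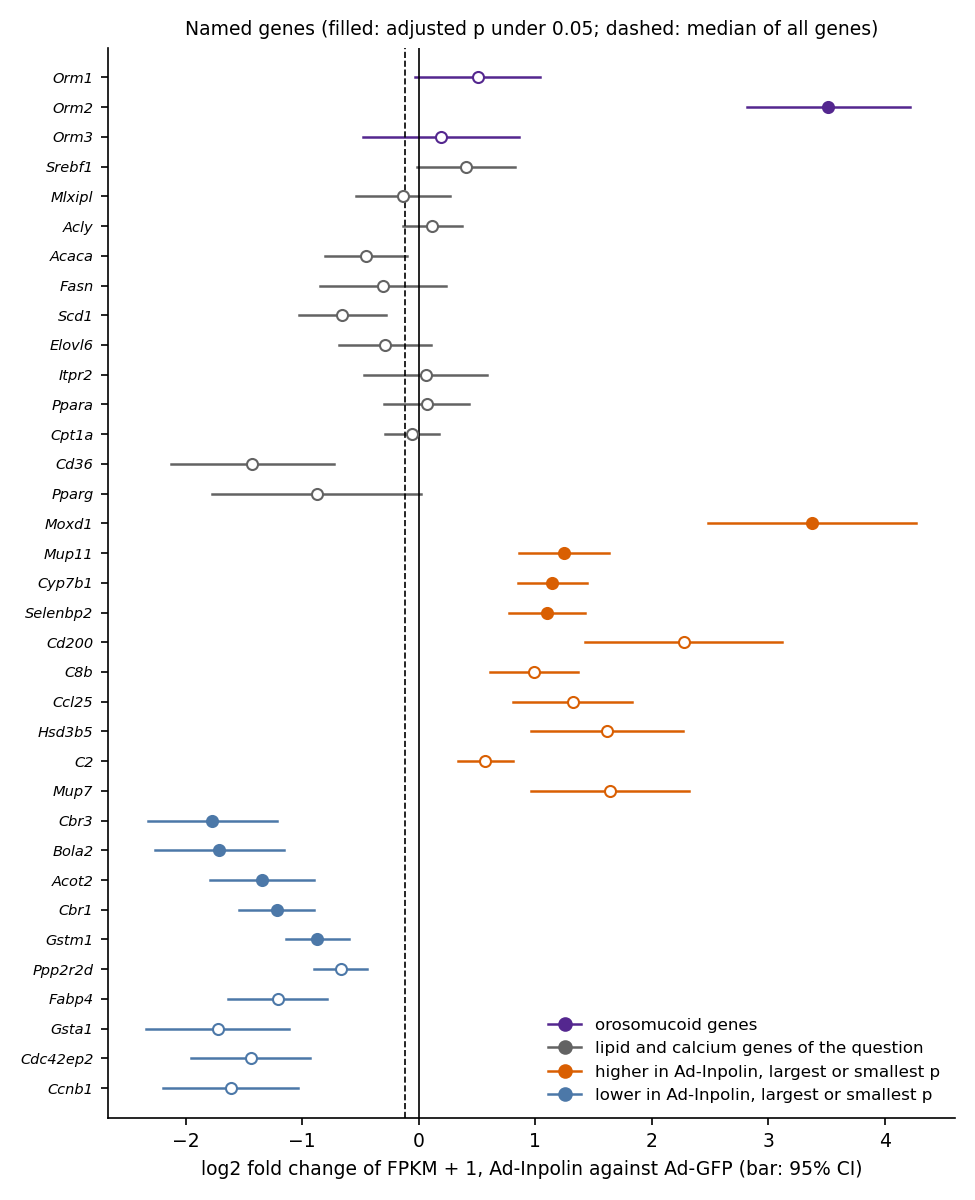
Log2 fold change of FPKM + 1 in Ad-Inpolin against Ad-GFP livers, as deposited, with its 95% CI for the orosomucoid genes, the lipid and calcium genes of the question and the genes with the largest or most certain changes (4 livers per group). Filled points passed an adjusted p of 0.05, the dashed line marks the median gene at -0.12, and Orm2, Moxd1, Mup11, Cyp7b1 and Selenbp2 are the filled points to the right.

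Groups of genes were compared with all other genes as 31 lists, of which 18 passed with the preset correlation between genes, 11 higher and 7 lower in Ad-Inpolin livers. Without Ad-Inpolin 3 the number was 14, and with a correlation estimated from these data 1 list passed, the male-biased genes. Leaving out that liver also brought list medians nearer to 0 by more than 1.5-fold: acute-phase 0.51 to 0.32, periportal 0.51 to 0.33, general hepatocyte 0.26 to 0.15, pericentral 0.25 to 0.12, cholesterol synthesis 0.26 to 0.16, endoplasmic reticulum stress 0.28 to 0.16, bile acid 0.10 to 0.05, red cell 0.21 to 0.04, p53 -0.48 to -0.28 and female-biased -1.96 to -1.13.

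The lipogenesis question was addressed with 21 measured genes of fatty acid and triglyceride synthesis. As a group they did not differ from other genes. The median log2 fold change was 0.02 relative to the median gene, 11 members lay above that gene and 10 below, and the list test gave an adjusted p of 0.996. The mean of the list and the test pointed down while the median pointed up. By limma 0 members passed the threshold over all genes and 0 when adjusted over the list alone, with 5 lower and 0 higher at an unadjusted p under 0.05. Scd1, the desaturase that makes oleate, was at 1157 ± 80.7 FPKM in Ad-GFP and 752 ± 182 FPKM in Ad-Inpolin livers (SD, n = 4), with no overlap, a log2 fold change of -0.54 ± 0.17 and an adjusted p of 0.229. Acaca, acetyl-CoA carboxylase, was at 10.9 ± 0.679 and 7.81 ± 1.64 FPKM (log2 fold change -0.33, adjusted p = 0.317). The elongase Elovl5 and malic enzyme Me1 had log2 fold changes of -0.46 and -0.83 (adjusted p = 0.245 and 0.269). Fasn, fatty acid synthase, was at 24.8 ± 4.61 and 20.7 ± 7.87 FPKM (adjusted p = 0.638), and Elovl6 at 26.1 ± 1.88 and 21.8 ± 6.35 FPKM (adjusted p = 0.546). The lipogenic transcription factor Srebf1 was at 16.2 ± 2.86 and 22.0 ± 4.98 FPKM (log2 fold change 0.52, adjusted p = 0.431), and Mlxipl, which encodes ChREBP, at 52.8 ± 4.13 and 49.4 ± 13.4 FPKM (adjusted p = 0.791). Acly, ATP citrate lyase, was at 32.4 ± 3.16 and 35.2 ± 3.02 FPKM (adjusted p = 0.699). In data simulated on these genes, 58.36% of genes changed 2-fold and 18.36% of genes changed 1.5-fold were recovered, so changes of the size of that of Scd1 were mostly below what 4 livers per group could call.

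Genes of calcium release and AMPK signalling did not differ as a group (14 tested, median log2 fold change 0.01, adjusted p = 0.949). Itpr2, the main hepatocyte IP3 receptor, was at 4.54 ± 0.541 FPKM in Ad-GFP and 5.02 ± 2.28 FPKM in Ad-Inpolin livers (SD, n = 4; adjusted p = 0.940). By limma 0 of the 14 members passed over all genes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05.

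Genes of lipid droplets and fatty acid uptake were lower in Ad-Inpolin livers as a group, but Ad-Inpolin 4 lay close to the Ad-GFP livers. By liver the list median was -0.52, -0.47, -0.72 and -0.13 in Ad-Inpolin 1 to Ad-Inpolin 4, against -0.11 to 0.18 in Ad-GFP livers. Of 18 members, 15 lay below the median gene, the list median was -0.50 and the list adjusted p was 0.000237 (adjusted p = 0.295 with an estimated correlation). Fabp4, a fatty acid carrier, was at 88.4 ± 11.9 FPKM in Ad-GFP and 38.6 ± 11.4 FPKM in Ad-Inpolin livers. The fatty acid transporter Cd36 was at 106 ± 8.99 and 43.0 ± 20.1 FPKM (log2 fold change -1.31 ± 0.32, adjusted p = 0.163), the droplet coat gene Plin2 at 470 ± 36.7 and 284 ± 87.4 FPKM (adjusted p = 0.239), and Dgat1, which makes triglyceride, at 13.3 ± 1.56 and 8.67 ± 2.82 FPKM (all SD, n = 4). Fabp4, Cd36 and Plin2 passed when adjusted over the list alone, whereas by limma 0 members passed over all genes and 8 were lower at an unadjusted p under 0.05. Pparg, a driver of lipid storage genes, was at 18.8 ± 4.43 and 11.3 ± 6.54 FPKM (adjusted p = 0.425). Without Ad-Inpolin 4, Cd36 passed over all genes (adjusted p = 0.0402, against up to 0.427 in other alternatives).

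Fatty acid oxidation and ketogenesis genes were also lower as a group, again with Ad-Inpolin 4 close to the Ad-GFP livers. By liver the list median was -0.25, -0.15, -0.33 and -0.11 in Ad-Inpolin 1 to Ad-Inpolin 4, against -0.11 to 0.04 in Ad-GFP livers. Of 25 members, 22 lay below the median gene, with a list median of -0.17 and a list adjusted p of 5.78e-07 (adjusted p = 0.295 with an estimated correlation). Acot2 was the 1 member past the threshold over all genes, and 7 members were lower when adjusted over the list alone. Among these were Ehhadh, the peroxisomal bifunctional enzyme, at 164 ± 10.3 and 81.6 ± 35.8 FPKM (log2 fold change -0.99), the cytosolic thioesterase Acot1 at 13.8 ± 3.47 and 7.24 ± 2.06 FPKM, and Acadl, long-chain acyl-CoA dehydrogenase, at 147 ± 7.87 and 118 ± 7.31 FPKM (SD, n = 4). Ehhadh passed over all genes without Ad-Inpolin 4 (adjusted p = 0.0273, against up to 0.427). Ppara, the transcription factor that drives many of these genes, was at 17.2 ± 2.90 and 18.1 ± 3.68 FPKM (adjusted p = 0.895), and Cpt1a, which gates mitochondrial entry, at 101 ± 11.7 and 96.8 ± 2.56 FPKM (adjusted p = 0.845).

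Cholesterol synthesis genes lay above the median gene in 20 of 23 cases, with a list median of 0.26 and a list adjusted p of 0.000394 (adjusted p = 0.365 with an estimated correlation). No member passed by limma: 0 over all genes, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. Fdps was at 41.4 ± 9.17 and 58.6 ± 16.1 FPKM and Sqle, squalene epoxidase, at 10.2 ± 2.32 and 15.4 ± 5.67 FPKM, while Hmgcs1 was at 119 ± 12.4 and 101 ± 30.5 FPKM (SD, n = 4). In Ad-Inpolin 4 the list median was -0.24, against 0.22 to 0.47 in the other 3 Ad-Inpolin livers. Lipoprotein genes did not pass (17 tested, median 0.11, adjusted p = 0.229) except, as higher, without Ad-Inpolin 1 (adjusted p = 0.0323). By limma 0 of them passed over all genes or adjusted over the list alone, and 1 was higher and 1 lower at an unadjusted p under 0.05. Among them Apoa1 was at 3998 ± 227 and 5513 ± 1868 FPKM and Apoc2 at 294 ± 29.3 and 209.9 ± 51.4 FPKM (SD, n = 4).

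As a list, genes expressed more in male than in female liver were higher in Ad-Inpolin livers. The 5 measured genes of the female-biased list were lower as a list with the preset correlation only, and 1 of them lay above the median gene. Of 15 male-biased members, 13 lay above the median gene and the list median was 0.53. The list adjusted p was 9.08e-11, and this was the 1 list of 31 that also passed with an estimated correlation (adjusted p = 0.00962). Cyp7b1 and Selenbp2 rose over all genes, and 7 members passed when adjusted over the list alone. Among these, Hsd3b5 was at 21.5 ± 7.04 and 70.3 ± 30.5 FPKM (log2 fold change 1.74) and Mup1 at 40.1 ± 4.91 and 88.3 ± 27.1 FPKM (log2 fold change 1.19; SD, n = 4). The list median was 0.63, 0.59, 1.18 and 0.32 in the Ad-Inpolin livers, and the 1.18 was in Ad-Inpolin 3. Mup1 passed over all genes without Ad-Inpolin 2 (adjusted p = 0.0259, against up to 0.322).

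Of the female-biased list 5 of 13 members could be tested, 4 lay below the median gene, the list median was -1.96 and the list adjusted p was 0.000394 (adjusted p = 0.251 with an estimated correlation). The median rests on few genes: it was -1.13 without Ad-Inpolin 3, -1.27 without Ad-GFP 4 and -0.05 with no filter. Cyp2a4, a steroid hydroxylase, was at 32.2 ± 11.4 FPKM in Ad-GFP and 4.13 ± 3.31 FPKM in Ad-Inpolin livers, a log2 fold change of -2.83 ± 0.50 (adjusted p = 0.0663). Cyp2b9 was at 22.4 ± 6.31 and 4.58 ± 3.22 FPKM (log2 fold change -2.09, adjusted p = 0.0663) and the thioesterase Acot3 at 17.8 ± 8.77 and 3.32 ± 1.52 FPKM (log2 fold change -1.96, adjusted p = 0.0587; all SD, n = 4). These 3 passed when adjusted over the list alone, and Cyp2b13 did not (adjusted p = 0.480 over all genes). Without Ad-Inpolin 4 they also passed over all genes, with adjusted p of 0.0208, 0.0130 and 0.0273, and Cyp2a4 did so without Ad-Inpolin 3 (adjusted p = 0.0493), alone or with median-ratio scaling (0.0439). With library weights they passed at 0.0279, 0.0360 and 0.0489, and with the filter at 5 FPKM Acot3 passed at 0.0348. Over their alternatives the adjusted p reached 0.233, 0.268 and 0.218.

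Drug-metabolising genes moved in both directions and lower as a group. By liver the list median was -0.51, -0.36, -0.47 and -0.07 in Ad-Inpolin 1 to Ad-Inpolin 4, against -0.03 to 0.08 in Ad-GFP livers. The list shares Cyp2b9 and Cyp2b13 with the female-biased list and Cyp1a2 and Cyp2e1 with the pericentral list, so these calls are not separate. Of 21 members, 13 lay below the median gene, with a list median of -0.26 and a list adjusted p of 0.00243 (adjusted p = 0.295 with an estimated correlation). Gstm1 fell over all genes, and 10 members were lower and 1 higher when adjusted over the list alone. The glutathione transferases Gsta1 and Gstm3 were at 25.3 ± 5.09 and 45.3 ± 7.30 FPKM in Ad-GFP livers and at 7.41 ± 3.62 and 15.9 ± 7.25 FPKM in Ad-Inpolin livers (SD, n = 4). The log2 fold changes were -1.61 and -1.42, and Gstm3 passed over all genes without Ad-Inpolin 4 (adjusted p = 0.00416), with library weights (0.0279) and with the filter at 5 FPKM (0.0382), against up to 0.233 in other alternatives. In the bile acid list, which shares Cyp7b1 and Slco1a1 with the male-biased list, 13 of 19 members lay above the median gene (median 0.10, adjusted p = 0.0214; adjusted p = 0.223 with an estimated correlation). Cyp7b1 rose over all genes. When adjusted over the list alone 2 members were higher and 3 lower, the latter including the canalicular phospholipid exporter Abcb4 at 96.2 ± 8.09 and 65.8 ± 18.4 FPKM and Abcc3 at 32.2 ± 9.19 and 20.0 ± 5.01 FPKM, while the uptake carrier Slco1a1 was at 49.99 ± 0.692 and 101 ± 50.2 FPKM (SD, n = 4). The bile acid call was lost without Ad-Inpolin 3 (adjusted p = 0.296), with quantile scaling (0.145) and with library weights (0.0981), and Slco1a1 passed over all genes without Ad-Inpolin 4 (adjusted p = 0.0410, against up to 0.554).

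The periportal, general hepatocyte and pericentral lists were higher in Ad-Inpolin livers with the preset correlation. Cps1 and Arg1 stand in both the periportal and the general hepatocyte list, so these calls are not separate. Periportal genes, expressed near the portal vein where urea is made, lay above the median gene in 10 of 12 cases (median 0.51, adjusted p = 1.07e-07; adjusted p = 0.223 with an estimated correlation). By limma 0 of them passed over all genes, but 9 were higher and 2 lower when adjusted over the list alone, as at an unadjusted p under 0.05. The urea cycle genes Cps1 and Ass1 were at 315 ± 28.8 and 410 ± 24.9 FPKM in Ad-GFP and at 459 ± 86.0 and 573 ± 121 FPKM in Ad-Inpolin livers, and serine dehydratase, Sds, at 67.4 ± 10.8 and 116 ± 36.3 FPKM (SD, n = 4). General hepatocyte genes lay above the median gene in 13 of 15 cases (median 0.26, adjusted p = 1.37e-05; adjusted p = 0.223 with an estimated correlation). The mean of this list was 0.01, since it includes Alb, named here because its values were seen. Alb was at 21764, 29008, 27383 and 26211 FPKM in the Ad-GFP livers and at 25106, 23130 and 20120 FPKM in Ad-Inpolin 1, Ad-Inpolin 2 and Ad-Inpolin 4, and was listed at 0 in Ad-Inpolin 3 (adjusted p = 0.699). Among the others Serpina1a was at 1038 ± 53.6 and 1465 ± 301 FPKM and prothrombin, F2, at 480 ± 19.7 and 574 ± 70.5 FPKM; 0 passed over all genes by limma, 3 were higher when adjusted over the list alone and 5 at an unadjusted p under 0.05. Pericentral genes lay above the median gene in 10 of 12 cases (median 0.25, adjusted p = 0.00252; adjusted p = 0.295 with an estimated correlation), with Cyp1a2 at 129 ± 8.78 and 173 ± 35.7 FPKM and Cyp2e1 at 3316 ± 349 and 3932 ± 631 FPKM (SD, n = 4). In Ad-Inpolin 3 the medians of these 3 lists were 0.93, 0.64 and 0.51, above the 0.06 to 0.44 of the other Ad-Inpolin livers. The pericentral call was lost without that liver (adjusted p = 0.0967), and the hepatocyte call with quantile scaling (adjusted p = 0.119).

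Acute-phase genes, secreted by the liver in inflammation, lay above the median gene in 22 of 24 cases with Orm2 left out (median 0.51, adjusted p = 1.26e-10; adjusted p = 0.282 with an estimated correlation). Saa4, a constitutive serum amyloid gene, was at 215 ± 15.5 FPKM in Ad-GFP and 387 ± 108 FPKM in Ad-Inpolin livers (log2 fold change 0.92), and it was the 1 member that passed when adjusted over the list alone. Haptoglobin, Hp, was at 2096 ± 211 and 2877 ± 704 FPKM and the fibrinogen gene Fgg at 2765 ± 312 and 3704 ± 841 FPKM (SD, n = 4). By limma 0 members passed over all genes and 7 were higher at an unadjusted p under 0.05. The list median ranged from -0.05 in Ad-Inpolin 4 to 0.94 in Ad-Inpolin 3, with 0.73 and 0.26 in Ad-Inpolin 1 and Ad-Inpolin 2, and without Ad-Inpolin 4 Saa4 passed over all genes (adjusted p = 0.0366, against up to 0.413).

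Interferon-induced genes lay above the median gene in 21 of 24 cases (median 0.27, adjusted p = 6.73e-07; adjusted p = 0.282 with an estimated correlation). The GTPase Ifi47 was at 34.5 ± 3.81 and 47.0 ± 5.89 FPKM, the chemokine Cxcl9 at 17.9 ± 3.77 and 27.2 ± 5.34 FPKM, and Irf7 at 32.0 ± 7.44 and 43.8 ± 5.92 FPKM (SD, n = 4). Endoplasmic reticulum stress genes lay above the median gene in 15 of 19 cases (median 0.28, adjusted p = 0.00135; adjusted p = 0.346 with an estimated correlation). Sdf2l1 and Hsp90b1 were at 16.9 ± 5.61 and 627 ± 34.2 FPKM in Ad-GFP and at 29.4 ± 7.74 and 746 ± 61.0 FPKM in Ad-Inpolin livers, and Atf4 and Ddit3 were at 65.0 ± 10.9 and 11.03 ± 1.04 FPKM and at 45.8 ± 7.26 and 8.65 ± 1.14 FPKM (SD, n = 4). In Ad-Inpolin 3 the stress list median was 0.56, against 0.11 to 0.18 in the other 3. In either list 0 members passed over all genes by limma or adjusted over the list alone, with 5 higher and 1 lower interferon genes and 2 higher and 2 lower stress genes at an unadjusted p under 0.05.

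Glucose and insulin response genes lay above the median gene in 14 of 17 cases (median 0.15, adjusted p = 0.0249; adjusted p = 0.223 with an estimated correlation). Pck1, the gatekeeper of gluconeogenesis, was at 637 ± 87.1 and 862 ± 187 FPKM and the glucose transporter Slc2a2 at 149 ± 10.1 and 116 ± 27.6 FPKM (SD, n = 4). Red cell genes lay above it in 6 of 7 cases (median 0.21, adjusted p = 0.0349; adjusted p = 0.365 with an estimated correlation), with the haem synthesis gene Alas2 at 30.6 ± 4.32 and 41.4 ± 5.76 FPKM. By limma 0 members of these 2 lists passed over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 1 glucose gene was higher and 1 lower, and 2 red cell genes were higher. The glucose call was lost without Ad-GFP 1 (adjusted p = 0.0786), Ad-GFP 2 (0.0505), Ad-Inpolin 2 (0.0849) or Ad-Inpolin 3 (0.170), and the red cell call without Ad-GFP 1 (0.306), Ad-GFP 3 (0.168) or Ad-Inpolin 3 (0.213), in which its median was 0.71 against 0.01 to 0.11 in the other Ad-Inpolin livers. Both were also lost with quantile scaling (0.160 and 0.132) and library weights (0.0766 and 0.0825), and the red cell call with median-ratio scaling (0.0546).

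Cell cycle genes were lower in Ad-Inpolin livers, and all 20 lay below the median gene (list median -0.44, adjusted p = 4.51e-06; adjusted p = 0.106 with an estimated correlation). Cdk1, the mitotic kinase, was at 15.9 ± 3.08 FPKM in Ad-GFP and 6.36 ± 2.32 FPKM in Ad-Inpolin livers (log2 fold change -1.12), and Ccnd1, cyclin D1, at 9.21 ± 0.579 and 5.23 ± 1.41 FPKM (SD, n = 4). Ccnb1, cyclin B1, was at 3.08, 3.23, 4.94 and 2.58 FPKM in the Ad-GFP livers and at 0.522 and 1.12 FPKM in Ad-Inpolin 1 and Ad-Inpolin 4 and at 0.3 FPKM in Ad-Inpolin 3, and was listed at 0 in Ad-Inpolin 2. These 3 passed when adjusted over the list alone, 0 members passed over all genes by limma, and 8 were lower at an unadjusted p under 0.05. All 12 p53 target genes also lay below the median gene (list median -0.48, adjusted p = 0.000742; adjusted p = 0.387 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 26.7 ± 2.49 and 15.6 ± 5.54 FPKM and Mdm2, which degrades p53, at 31.3 ± 3.61 and 20.2 ± 6.98 FPKM (SD, n = 4). By limma 0 p53 targets passed over all genes or adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. The p53 list median was -1.27 in Ad-Inpolin 3 and between -0.34 and -0.26 in the other Ad-Inpolin livers.

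Stellate cell and matrix genes lay below the median gene in 13 of 15 cases (list median -0.26, adjusted p = 0.00853; adjusted p = 0.387 with an estimated correlation). The collagen genes Col3a1 and Col1a1 were at 22.3 ± 5.99 and 4.23 ± 0.599 FPKM in Ad-GFP and at 13.0 ± 4.90 and 2.80 ± 0.417 FPKM in Ad-Inpolin livers (SD, n = 4). By limma 0 members passed over all genes or adjusted over the list alone, 5 were lower at an unadjusted p under 0.05, and the call was lost without Ad-Inpolin 2 (adjusted p = 0.0852).

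Markers of the other cells of the liver did not pass as groups in the fit to all 8 livers. The list adjusted p was 0.996 for endothelial cells, 0.592 for macrophages, 0.0731 for T and NK cells, 0.251 for B and plasma cells, 0.229 for neutrophils, 0.304 for bile duct cells and 0.289 for adipocytes, and 0.839 for antigen presentation genes. Among macrophage genes Cd14 was at 8.06 ± 1.60 and 4.48 ± 1.13 FPKM (adjusted p = 0.242), and Gpnmb at 4.01 ± 0.306 and 1.85 ± 1.499 FPKM (SD, n = 4; adjusted p = 0.287, and 0.0410 without Ad-Inpolin 4, against up to 0.554). Nuclear-encoded respiratory chain genes (adjusted p = 0.108) and mitochondrially encoded genes (adjusted p = 0.371) did not pass either. Some of these lists passed in an alternative. The respiratory chain list did so as lower with quantile scaling (adjusted p = 0.00498), with no filter (0.0481) and without Ad-Inpolin 2 (0.0243) or Ad-Inpolin 4 (0.0236), the neutrophil list as lower with the replicate block (0.0495) and without Ad-GFP 4 (0.0481), the macrophage list as lower without Ad-GFP 3 (0.0108), and the T and NK cell list as higher without Ad-GFP 1 (0.0172) or Ad-Inpolin 1 (0.0323). All 7 neutrophil genes lay below the median gene (median -0.40). The mitochondrially encoded list had a median of 0.05 but a mean of 1.39, raised by members listed at 0 in some livers. Of these mt-Co3 and mt-Nd4 were listed at 0 in Ad-GFP 1, Ad-GFP 2, Ad-GFP 3 and Ad-Inpolin 2, and were at 407 and 5670 FPKM in Ad-GFP 4, at 716 and 5937 FPKM in Ad-Inpolin 1, at 1713 and 5325 FPKM in Ad-Inpolin 3 and at 1706 and 5956 FPKM in Ad-Inpolin 4. The median and the mean or test pointed in different directions for the endothelial, macrophage and respiratory chain lists. By limma 0 members of these 10 lists passed over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 1 T and NK cell gene was higher, and 2 macrophage, 4 respiratory chain, 2 mitochondrially encoded and 1 each of the neutrophil, bile duct, adipocyte and antigen presentation genes were lower.

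**Figure D3:**
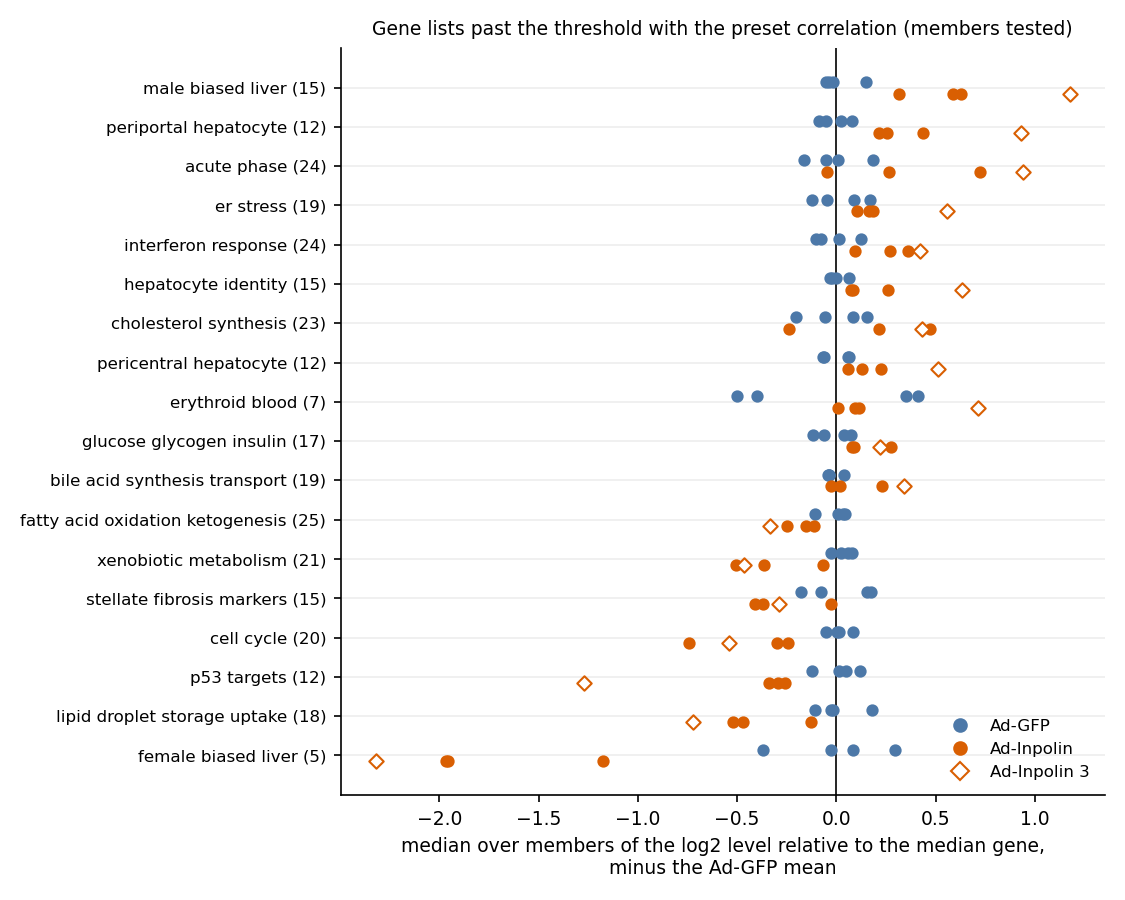
Median over the members of each of the 18 lists past the threshold with the preset correlation, as the log2 level relative to the median gene minus the Ad-GFP mean, with 1 point per liver (Ad-GFP blue, Ad-Inpolin orange, Ad-Inpolin 3 an open diamond) and the number of members in parentheses. The male-biased median was between 0.32 and 1.18 in Ad-Inpolin livers and the female-biased median, of 5 members, was between -2.32 and -1.17, and the p53 median was -1.27 in Ad-Inpolin 3 and between -0.34 and -0.26 in the other Ad-Inpolin livers.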

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

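A sample was marked here when its gap to the nearest of the other 3 livers of its group took up more of the range of the 4 than Dixon's 95% limit allows. Of 328 groups of 4 values, 24 were marked, where chance gives about 5%, and 10 of the 24 were in Ad-Inpolin 3. The depth and top-gene tests of the next paragraph were written after the values were seen, and the cell marker test before.

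The mean correlation of Ad-Inpolin 3 with the other libraries, 0.9468, lay below the 0.962 to 0.9635 of the other Ad-Inpolin livers (gap 0.911). The relative depth of Ad-Inpolin 3 was estimated at 94.3%, against a lowest of 84.1% elsewhere, which counted against lower sequencing depth. Only depths near that of Ad-GFP 1 were searched, however, and a depth lower by a whole-number ratio could be read as near it. This library also had the most genes at 0 (9780) and the lowest share on whole-read steps (15.6%). Lower depth therefore stays open. A few genes other than Alb taking most of the signal was not borne out, as the 10 most abundant of the genes above 0 in all libraries held 21.34% of their FPKM, against up to 22.43% in the others. For Alb this stays open, as it is listed at 0 there. A lower share of other cells would lower all 4 marker medians relative to the other 3 Ad-Inpolin livers. The medians were 0.206 (SE 0.109) for macrophages and 0.082 (SE 0.095) for endothelial cells. They were -0.088 (SE 0.139) for stellate cells and 0.324 (SE 0.178) for T and NK cells, most of whose genes lie below 4 FPKM. By the prediction, the macrophage median counted against such a share. Its SE is over genes within a single liver, however, and does not measure the spread between livers. Among Ad-GFP livers the macrophage list median ranged from -0.334 to 0.217, so a lower share of other cells stays open. A biological difference of this mouse remains possible and could not be tested, its Orm2 being the lowest of the group at 381 FPKM.

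Also apart in Ad-Inpolin 3, all as log2(FPKM + 1), were the secreted hepatocyte proteins Serpina1a (10.9 against at most 10.42 in the other 3, gap 0.841), Serpina1b (11.82 against 11.36, gap 0.903) and F2 (9.41 against 9.083, gap 0.955), all high. Pigr was high in it too (8.597 against 7.975, gap 0.864). Alb, the albumin gene, was listed at 0 in it and was at least 14.3 in the other 3 (gap 0.978). Low in it were the lipoprotein assembly gene Mttp (6.452 against at least 6.83, gap 0.837), the neutrophil gene S100a9 (4.313 against 4.938, gap 0.890) and the p53 targets Cdkn1a (3.065 against 4.195, gap 0.883) and Mdm2 (3.442 against 4.528, gap 0.856). Other Ad-Inpolin livers stood apart for Ms4a1, a B cell gene, high in Ad-Inpolin 4 (gap 0.848), Sox9, a bile duct gene, high in Ad-Inpolin 4 (gap 0.840), and Ddit3, low in Ad-Inpolin 2 (gap 0.830). Among Ad-GFP livers, Acly was high in Ad-GFP 2 (gap 0.923), C2 low in Ad-GFP 4 (gap 0.834), Abcc3 high in Ad-GFP 1 (gap 0.910), and Cxcr6 high in Ad-GFP 4 (gap 0.838). In Ad-GFP 3 the endothelial genes Lyve1 (gap 0.872) and Oit3 (gap 0.875) and the T cell gene Cd3d (gap 0.866) were low. The mitochondrial genes mt-Co3 and mt-Nd4, which every liver cell uses, were listed at 0 in Ad-GFP 1, Ad-GFP 2, Ad-GFP 3 and Ad-Inpolin 2. In Ad-GFP 4 they were at 407 and 5670 FPKM (gap 1 for both), and the gaps of the 0 in Ad-Inpolin 2 were 0.883 and 0.987. In Ad-GFP 1, Ad-GFP 2, Ad-GFP 3 and Ad-Inpolin 2 the mitochondrially encoded list median was -0.087, -0.012, 0.070 and 0.067. It was -0.060 to 0.062 in the other livers. The mitochondrial gene mt-Nd1 was at 18697, 18817, 19275 and 17124 FPKM in those 4. In Ad-Inpolin 3 the general hepatocyte list median was 0.635. These values argue against a general lack of mitochondrial or of hepatocyte transcripts in the livers with a 0. Whether a 0 of such a gene, or of Alb, is a failed quantification is not stated and was not tested.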

How the results depend on the processing

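Orm2 passed in all 18 alternatives, with adjusted p between 0.00015 and 0.0355. The male-biased list also passed in each, including an estimated correlation, and with fry. The count of 11 genes was 4 with no filter, 18 with the filter at 5 FPKM, 5 with median-ratio scaling, 26 with library weights, 2 without trend and robust, 1424 at an unadjusted p, and 1 to 57 leaving out 1 liver at a time. The 18 lists became 1 with an estimated correlation. With fry in one direction 2 lists passed, but fry tests a list against no change in the FPKM as deposited and camera against the other genes, so that count answers another question. With the replicate block 2 genes and 19 lists passed, neutrophil markers being the list gained (adjusted p = 0.0495); the numbers do not pair the livers (correlations of same-numbered deviations -0.031, 0.065, -0.03 and 0.051). The lowest mean correlation of a library was 0.9084 and 0.9372 with pseudocounts of 0.1 and 0.5, 0.9617 with no filter and 0.9317 with the filter at 5 FPKM. The lipogenesis list stayed uncalled but turned direction with pseudocounts of 0.1 (adjusted p = 0.966) and 0.5 (0.991), the filter at 5 FPKM (0.852) and the block (0.954), and in some fits that left out a liver (0.436 to 0.876, all such fits 0.254 to 0.976).

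Direction also turned for genes that passed in no fit, given here as log2 fold changes as deposited and not relative to the median gene. Leaving out 1 liver at a time gave Mlxipl -0.256 to 0.0381, Ppara -0.0587 to 0.170, Car3 -0.268 to 0.00788 and Spp1 -0.467 to 0.0848, turned without Ad-Inpolin 3, and Itpr2 -0.175 to 0.203 and Sox9 -0.318 to 0.0217, turned without Ad-Inpolin 2, Gstp1 -0.0984 to 0.0499, turned without Ad-Inpolin 1 or Ad-Inpolin 3, Socs2 -0.651 to 0.144, turned without Ad-GFP 1, and Igf1 -0.0619 to 0.0898, turned without Ad-GFP 2, Ad-GFP 4 or Ad-Inpolin 3. Ppara was -0.000599 without Ad-GFP 1. Without Ad-Inpolin 3 and with median-ratio scaling the values were Mlxipl 0.0953, Ppara -0.00359, Car3 0.0662, Spp1 0.143, Sox9 0.00760, Fech 0.0162, Gclm 0.00751 and Gstp1 0.108. Ppara was -0.00557 and Gstp1 0.0108 with library weights, Gclm 0.0166 and Gstp1 0.0893 with median-ratio and Igf1 -0.00974 with quantile scaling, Cpt1a 0.00379 with quantile and 0.0542 with median-ratio scaling, Sox9 0.0467 and Cyp2e1 -0.0430 with quantile scaling, and Fech 0.00177 with median-ratio scaling. Of these 31 turns 11 remain relative to the median gene of each fit: those of Itpr2, Spp1, Car3, Mlxipl and Socs2, that of Ppara without Ad-Inpolin 3, and those of Cyp2e1 and Igf1 with quantile scaling. The others kept their direction on that scale, on which 37 other values, of 11 genes, turned. Among the other gene values 2661 stayed the same, 43 became stronger and 98 weaker, and of the list values 505 stayed the same, 10 became stronger and 54 weaker, those by fry included. The camera test turned direction, without passing, for lists uncalled in the fit reported, given as list medians: adipocyte markers with no filter (0.0441), antigen presentation with quantile scaling (-0.0580) and library weights (0.0294), calcium and AMPK genes with the filter at 5 FPKM (-0.0591), endothelial markers with pseudocounts of 0.1 (0.0616) and 0.5 (0.0513), the filter at 5 FPKM (0.0372), quantile scaling (0.0355) and library weights (0.00368), lipoprotein genes with quantile scaling (-0.0605) and macrophage markers with the filter at 5 FPKM (0.0451). By fry the direction against no change was the opposite of that by camera for antigen presentation, calcium and AMPK, lipoprotein and mitochondrially encoded genes, whose medians are those of the fit reported (0.0638, 0.0127, 0.110 and 0.0532), so these are not turns of the same comparison. The camera direction also turned in some fits that left out 1 liver, over which the medians lay from -0.0144 to 0.120 for antigen presentation, -0.0533 to 0.0683 for calcium and AMPK, -0.0439 to 0.0628 for endothelial and -0.151 to 0.144 for macrophage genes. The cause was not tested. Depth limits low genes most, and its absolute level is unknown. Its estimate was at most 94.3% of that of Ad-GFP 1 in Ad-Inpolin libraries and at least 94.6% in Ad-GFP libraries. Whether this lowered low genes in Ad-Inpolin livers, such as the low members of the cell cycle list, was not tested. Tests for read counts and the authors' own p values were planned but not run, since the table holds neither.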

Other observations

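Genes induced by NRF2, a transcription factor that answers oxidative and electrophile stress, lay lower in Ad-Inpolin livers as a list with the preset correlation (camera p = 7.66e-10) but not with an estimated one (0.0964). The list was chosen after seeing the 60 genes of smallest p, which were left out of it, and its prediction was written before its own values were examined. Of 25 tested members 22 lay below the median gene, with a list median of -0.41, and 19 were lower at an unadjusted p under 0.05. Txnrd1, thioredoxin reductase, was at 42.5 ± 6.10 FPKM in Ad-GFP and 29.1 ± 3.96 FPKM in Ad-Inpolin livers, Hmox1, haem oxygenase, at 28.8 ± 9.46 and 16.9 ± 4.48 FPKM, Ugdh at 128 ± 12.5 and 79.0 ± 21.5 FPKM, and Nqo1 at 9.42 ± 1.97 and 5.34 ± 2.36 FPKM (SD, n = 4). Gclm, a glutathione synthesis gene, was at 114 ± 10.95 and 106 ± 11.2 FPKM. As a hypothesis, NRF2 activity may be lower in Ad-Inpolin livers. Without the 4 members that also stand in an earlier list (Nqo1, Gsta2, Gstp1 and Abcc3) the camera p was 8.48e-09 with the preset and 0.0917 with an estimated correlation. The prediction was thus met only under the preset correlation. The list was picked from genes seen in these same livers, and the estimated correlation of its members was 0.464. Members may therefore have moved with the genes left out. It also keeps Gstm2, Gstm4, Gsta2 and Gsta4, of the same families as Gstm1 and Gsta1. The p is therefore not independent support for the hypothesis. NRF2 itself was not measured as a protein.

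Growth hormone acts in liver through STAT5 and sets much of its sex bias. Among 12 of its target or pathway genes outside the sex-biased lists, the list median was 0.33 and 3 were higher at an unadjusted p under 0.05. Egfr was at 52.0 ± 13.8 and 84.9 ± 22.5 FPKM, Pigr, the immunoglobulin carrier, at 184 ± 18.1 and 277 ± 72.8 FPKM, and Igfals at 10.05 ± 3.99 and 14.7 ± 0.705 FPKM, whereas the direct targets Socs2 and Cish were at 11.4 ± 7.94 and 2.87 ± 2.56 FPKM in Ad-GFP and at 8.45 ± 3.50 and 0.993 ± 0.181 FPKM in Ad-Inpolin livers, and Igf1 at 345 ± 50.1 and 349 ± 29.0 FPKM (SD, n = 4).

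For the opposite movement of the male-biased and female-biased lists, the tests of Ad-Inpolin 3 and of scaling were written after the values were seen, and those of shared reads and of STAT5 before. The library Ad-Inpolin 3 alone was not borne out, as the male-biased list kept a camera adjusted p of 4.71e-10 without it. Under quantile and median-ratio scaling the highest camera adjusted p of the 2 lists was 0.000104, so the prediction for scaling was not met. Camera compares a list with the other genes, however, and such scaling moves most genes of a library much alike. That test could therefore hardly show scaling as the cause, and nothing is concluded from it. For the male-biased list, reads shared among Mup genes or among Cyp4a12 genes were not borne out, as the 10 members other than Mup and Cyp4a12 genes gave a camera p of 1.46e-12 (0.00271 with an estimated correlation). Sharing of reads within other families, such as those of Selenbp2 and Hsd3b5, and for the female-biased Cyp2a4, Cyp2b9 and Acot3 was not tested and stays open. As a hypothesis, growth hormone and STAT5 signalling may differ between the groups: the camera p of the STAT5 genes was 0.000212 (0.0454 with an estimated correlation), and 0.000763 (0.0586) without Cyp8b1, which stands in an earlier list. The prediction was met, but the list mixes targets with pathway genes, and no direction under STAT5 activity was set for each gene. Bcl6 and Prlr thus counted toward this p as higher (0.47 and 0.40 relative to the median gene). The direct targets Socs2 and Cish were not higher. The p therefore does not show in which direction STAT5 signalling would differ.

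Whether any grouping of the livers would do as well was tested with all 35 splits, by predictions written before. The labelled split alone gave as many as 11 genes (1 of 35, highest other 4), as many as 18 lists (1 of 35, highest other 15) and as small a p for the male-biased list (1 of 35, 2.93e-12 against 3.68e-08). Other splits thus gave up to 15 lists, but those with 12 or more all kept 3 livers of a group together. Such splits carry part of the labelled difference. Splits with as many livers of either group on each side gave at most 11 lists. Up to 11 lists thus passed in splits balanced for group, so the number of lists by itself separates the groups little. The male-biased list had the smallest p of all lists in the labelled split. It was compared only with itself in other splits, not with the best list of each, so its 1 of 35 makes no allowance for that choice. Of the other 17 lists, the splits with as small a p numbered 1 for periportal, general hepatocyte, cell cycle and female-biased genes, 2 for fatty acid oxidation, 3 for interferon, lipid droplet and drug metabolism, 4 for p53, 5 for stellate, 7 for endoplasmic reticulum stress and glucose, 8 for acute-phase and pericentral, 10 for bile acid and 12 for cholesterol and red cell genes.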
